A study of Mus musculus with 2 samples.

How the data were processed

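Single-cell RNA sequencing had been run on CD45-positive cells sorted by flow cytometry from B16-hAXL tumours, grown from a mouse melanoma line whose name is read here as carrying human AXL. The mice had received either PBS or 200 µg of the anti-AXL antibody 6C5 by intraperitoneal injection, and tumours were labelled day 15. There was 1 library per group, and the number of mice behind each library is not given in the sources used here. Tumours were digested with collagenase and DNase, and libraries were made with a Chromium Single Cell v3 kit of 10x Genomics, per the labels' protocols.

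The deposited matrices hold raw UMI counts per gene and barcode, with no normalization, for 32285 genes. They are unfiltered: 546897 barcodes were listed for PBS and 566018 for 6C5. The counts were made with Cell Ranger 7.1.0 per the file headers, whereas the submitters' processing notes name Cell Ranger 2.1.1 and the mm10 genome build. Whether intronic reads were counted is not given in the sources used here. Symbols and identifiers were taken from the deposited gene table, and positions from GENCODE mouse release 21, which is on the same build (GRCm38, mm10).

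Cell calling began from the deposited counts. Barcodes with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs were kept, 13992 in PBS and 13541 in 6C5. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold marked 1 barcode in PBS and 0 in 6C5, so it had not worked, and the highest-scoring barcodes were removed instead at 0.8% per 1000 cells, 1566 in PBS and 1467 in 6C5. These were 11.2% and 10.8% of the barcodes kept. The rate counted every barcode as a cell, including those later set aside as like free RNA, so it may be too high. The 12426 PBS and 12074 6C5 barcodes left were clustered together with no batch integration, from the log of counts per 10000, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2).

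Clusters were named from marker genes fixed before the data were examined, and needed at least 3 markers among their leading genes. A cluster whose summed profile correlated at 0.98 or more with the free RNA of its library, taken from barcodes with 10 to 100 UMIs, stayed unnamed. That bound was set after the data had been seen. It set aside 6680 PBS barcodes (53.8%) and 6264 6C5 barcodes (51.9%), with median UMI counts of 895 and 1341. Another 1343 PBS and 810 6C5 barcodes stayed unnamed because markers were too few or mixed, clusters too small, or UMIs low. The low-UMI cluster held 501 PBS and 84 6C5 barcodes, with a median of 701 UMIs, and was led by Lyve1, Fcna and Gas6. It had 8 macrophage markers among its leading genes but none among the first 10, and counts of macrophage-like cells leave it out. Subclusters led by genes of another lineage were called mixed and left out, 203 barcodes in PBS and 248 in 6C5, also a choice made after the data had been seen. The T and NK classes, and the monocyte, macrophage and DC classes, were then clustered again for subclasses. Names are rebuilt from markers, since no annotation by the authors was used here.

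Shares of cells have exact Clopper-Pearson 95% intervals, and ratios of shares a 95% interval on the log scale. For expression, UMIs were summed per library and class and given per 1000000 of the class's UMIs (CPM). The ratio of 6C5 over PBS has an exact conditional binomial 95% interval. All of these intervals cover counting error only. With 1 library per group no test across samples was possible, and differences have no replicate check. A gene listed at 0 UMIs in a library was given a bound with 3 counts in that library. Classes with at least 100 cells in each library were compared.

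Gene lists were fixed before the data were examined. A list's value is the median log2 ratio (CPM plus 1) of members with at least 30 UMIs, with its percentile among 10000 random lists of equal size matched on mean expression in 20 bins. Members are counted as higher or lower where their counting interval excludes a ratio of 1. Every list measured in the 6 classes compared is given, and lists of subclasses, B-like and melanoma-like cells only in part. Those described with examples were picked after their values had been seen. Genes named are, per class, a fixed set of genes of interest. Up to 4 members of each described list with the largest absolute log2 ratio were added. The 6 highest and 6 lowest genes with at least 200 UMIs were named too. That ranking left out mitochondrial, ribosomal protein, haemoglobin, T-cell receptor, immunoglobulin and sex-linked genes, and markers of other classes. This rule was also fixed beforehand.

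Shares of T and NK cells with a UMI of a gene were taken after thinning each cell to 1000 UMIs, leaving out shallower cells. The share of free RNA in each class was estimated from melanoma and haemoglobin genes. TMM factors came from edgeR 4.0.16 in R 4.3.3. The steps were tested on simulated counts with 200 genes changed by known folds. For monocytes and macrophages, over 12257 genes, the interval excluded 1 in the right direction for 87.2% of genes changed 1.5-fold and 95.6% of genes changed 2-fold, and excluded 1 for 4.41% of unchanged genes. For T cells, over 9458 genes, these were 63.4%, 83.1% and 4.25%. Of 100 unchanged random lists, 5 lay outside the central 95% in monocytes and macrophages and 13 in T cells. Both simulated libraries were drawn from a single pooled profile with counting error alone, as the intervals assume. These rates therefore do not cover differences between mice, libraries, free RNA or the makeup of a class.

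Alternatives covered the cell filter, cell calling, doublets, cluster resolution, number of variable genes, separate clustering, scaling, weighting of cells, free RNA, list filters and pseudocount. Others were added after the data had been seen.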

Results

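The data were UMI counts from 1 library of CD45-positive tumour cells per group, PBS and 6C5. The question, from the series title, was how a membrane-proximal antibody against AXL reshapes the immune cells of a tumour. AXL is a receptor tyrosine kinase of the TAM family, which binds the ligand Gas6 and takes part in the clearance of dying cells. The PBS library held 78923567 UMIs and the 6C5 library 85921419. CPM below means UMIs of a gene per 1000000 UMIs of its class. Named immune cells numbered 4024 in PBS and 4370 in 6C5, with median depths of 9268.5 and 6905.5 UMIs. Their median mitochondrial share was 0.637% in PBS and 0.302% in 6C5, and it was lower in the 6C5 library in every class. Unnamed barcodes made up 64.6% of the PBS barcodes that passed the filter and 58.6% of the 6C5 barcodes. Each group has 1 library, so every difference below compares these libraries and has no replicate check, and intervals cover counting error only.

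Neutrophil-like cells made up a larger share of named immune cells in the 6C5 library and DC-like cells a smaller share. Neutrophil-like cells were 13.1% of named immune cells in PBS (528 of 4024) and 24.2% in 6C5 (1059 of 4370), a ratio of 1.85 (1.68 to 2.03). DC-like cells were 19.1% (17.9 to 20.3) in PBS and 10.5% (9.63 to 11.5) in 6C5, a ratio of 0.552 (0.496 to 0.615). T-like cells were 7.78% in PBS and 9.08% in 6C5 (ratio 1.17, 1.01 to 1.35), and that interval included 1 in 2 of 12 other settings. Monocyte-like and macrophage-like cells together were the largest class, at 45.4% and 43.3% (ratio 0.955, 0.910 to 1.00). That interval excluded 1 in 7 of 12 other settings, and the direction turned in 1. For NK-like cells (6.44% and 5.68%), B-like cells (6.29% and 5.45%) and plasmacytoid DC-like cells (1.94% and 1.69%) the interval of the ratio included 1. It excluded 1 in 3 of 12 other settings for NK-like cells and in 1 of 11 for B-like cells. With order-of-magnitude cell calling NK-like cells turned to 2.09 (1.64 to 2.66). That setting required at least 6887 UMIs in PBS and 8752 in 6C5. These minima lie above the median depths of NK-like (4457 and 5295.5) and neutrophil-like cells (2596 and 2562), so most of them were left out. The size of the neutrophil ratio depended on processing: it was 1.26 at resolution 2 and 3.56 with order-of-magnitude cell calling. These are shares of CD45-sorted cells with at least 500 UMIs, from libraries of unequal depth.

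**Figure D1:**
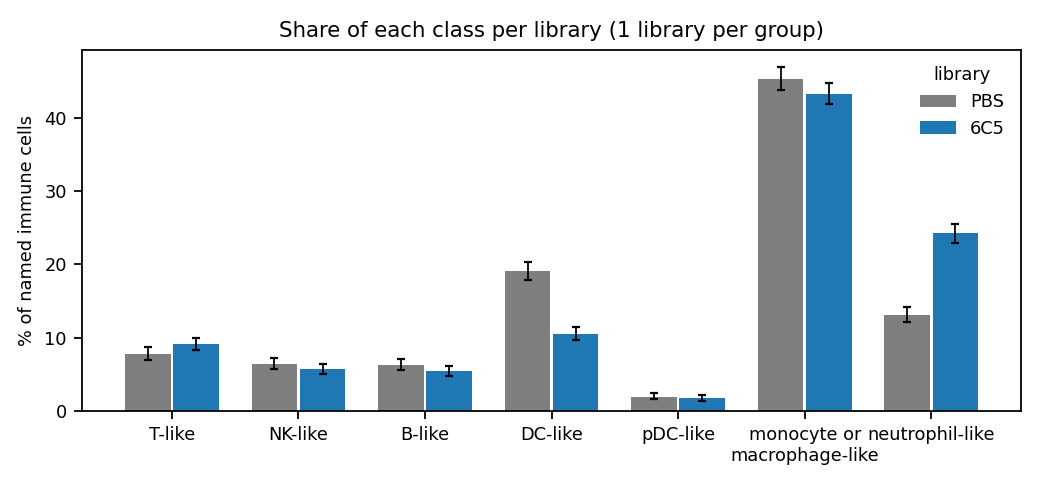
Share of each named class among named immune cells (%, vertical axis) in the PBS (grey) and 6C5 (blue) libraries. Bars are 1 library each and error bars are exact 95% binomial intervals for counting error only. The neutrophil-like bar stands at 13.1% in PBS and 24.2% in 6C5, and the DC-like bar at 19.1% and 10.5%.

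Among T and NK cells, the share of regulatory T-like cells was larger in the 6C5 library, and that of CD8 T-like cells was larger in most settings. CD8 T-like cells were 204 of 572 cells in PBS (35.7%) and 283 of 645 in 6C5 (43.9%), a ratio of 1.23 (1.07 to 1.42). Regulatory T-like cells were 35 and 61 cells (6.12% and 9.46%, ratio 1.55, 1.04 to 2.31). CD4 T-like cells were 60 and 40 (10.5% and 6.20%, ratio 0.591, 0.403 to 0.868), a subclass that was named in only 7 of 12 other settings. NK-like cells were 45.3% and 38.4% (ratio 0.849, 0.744 to 0.970), and gamma-delta T-like or ILC-like cells 14 and 13 cells (ratio 0.823, 0.390 to 1.74). There were 5.83 CD8 T-like cells per regulatory T-like cell in PBS (4.06 to 8.60) and 4.64 in 6C5 (3.51 to 6.22), and the interval of their ratio, 0.796 (0.506 to 1.25), included 1. That interval excluded 1 in 3 of 12 other settings, down to 0.473 (0.349 to 0.640) with 1000 variable genes. The CD8 interval included 1 in 5 of the 12 settings and the regulatory T interval in 4. With mixed subclusters kept, the counts of CD8 and regulatory T-like cells, and their ratio, were unchanged. That setting therefore cannot show what the removal did to them. A removed subcluster (49 PBS, 119 6C5 barcodes) had 0.857 of the regulatory T markers and 0.636 of the macrophage markers among its leading genes. Counting its barcodes as regulatory T-like was not tested. With order-of-magnitude cell calling the direction turned for CD8 T-like (0.774) and NK-like cells (1.18).

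Among monocytes, macrophages and DCs, both conventional DC subclasses had smaller shares in the 6C5 library. cDC1-like cells, the cross-presenting type, were 11.1% in PBS and 5.35% in 6C5 (ratio 0.480, 0.393 to 0.588). cDC2-like cells were 12.9% and 7.05% (ratio 0.547, 0.458 to 0.654), but 0.888 (0.764 to 1.03) with each library clustered on its own. Mature DC-like cells were 5.55% and 7.14% (ratio 1.29, 1.04 to 1.59), and that interval included 1 in 4 of 12 other settings. Monocyte-like cells were 8.95% and 22.3% (ratio 2.49, 2.15 to 2.87), and macrophage-like cells 61.5% and 58.2% (ratio 0.947, 0.904 to 0.991). The split between monocyte-like and macrophage-like cells turned direction under 5 settings, with monocyte ratios from 0.634 to 0.770, so no direction is read from it. A subcluster of 323 PBS and 193 6C5 cells had the monocyte marker Vcan and no macrophage marker among its 10 leading genes. It was counted as macrophage-like because 0.545 of the macrophage markers and 0.444 of the monocyte markers were among its 200 leading genes. Another, of 37 PBS and 400 6C5 cells, had the platelet gene Ppbp and no monocyte marker among its 10 leading genes against the other subclusters. Against other lineages the monocyte marker Chil3 was among its 10. It was counted as monocyte-like, with 0.444 of the monocyte markers and 0.273 of the macrophage markers among the 200.

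In monocyte-like and macrophage-like cells (1826 in PBS, 1894 in 6C5), type I interferon-stimulated, inflammatory and hypoxia genes were higher in the 6C5 library and cell cycle genes lower. Arginase 1 (Arg1), which depletes arginine, was at 88.8 CPM in PBS and 907 in 6C5, a ratio of 10.2 (9.78 to 10.7). Nos2, the inducible nitric oxide synthase that uses the same amino acid, was 14.2-fold higher (10.9 to 18.9), and the secreted phosphoprotein Spp1 8.54-fold higher (8.37 to 8.71). Among TAM genes, Axl was at 124 CPM in PBS and 87.7 in 6C5 (ratio 0.706, 0.667 to 0.747), and its ligand Gas6 at 115 and 23.5 (ratio 0.203, 0.185 to 0.223). A macrophage-like subcluster led by Gas6 and Lyve1 held 256 PBS and 89 6C5 cells. The ratios of both genes in this class therefore also carry the share of that subcluster. Mertk was at 47.5 and 40.5 (ratio 0.853, 0.782 to 0.930), a direction that turned with TMM factors (log2 ratio 0.08). The median of all genes in this class was -0.30 on the log2 scale, and TMM factors moved it to -0.03. In the mm10 build Axl lies on chromosome 7 (25757273 to 25788705, minus strand), Gas6 on chromosome 8 (13465374 to 13494490, minus strand) and Arg1 on chromosome 10 (24915221 to 24927484, minus strand).

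Type I interferon-stimulated genes had a median log2 ratio of 0.98 in this class, with 19 of 20 measured members higher, 1 lower and the median at percentile 100 of the random lists. The median was 0.60 in macrophage-like subclusters alone (19 of 20 higher, 1 lower) and 1.58 in monocyte-like subclusters alone. Monocyte-like cells were 232 in PBS and 524 in 6C5, so the value of the whole class also carries that split. Isg20 (log2 ratio 2.03), Rsad2 (1.87), Isg15 (1.67) and Usp18 (1.54) had the largest ratios. The inflammatory list had a median of 0.97 (15 of 16 higher, percentile 100), led by Nos2 (3.34) and the neutrophil-attracting chemokines Cxcl3 (2.60), Cxcl1 (1.95) and Cxcl2 (1.66). Chemokines that recruit leukocytes had a median of 0.82 (9 of 12 higher, 2 lower, percentile 100), with Ccl5 at 1.39, Ccl8 at 1.23 (3.87 in monocyte-like subclusters alone) and Cxcl10 at 0.99. The B-cell chemokine Cxcl13 went the other way, with 379 UMIs in PBS and 0 in 6C5, at least 107-fold lower. Cxcl9, a T-cell chemokine induced by interferon gamma, had a ratio of 0.997 (0.960 to 1.03), but was higher in monocyte-like subclusters alone (log2 ratio 1.70). Hypoxia and glycolysis genes had a median of 0.73 (16 of 17 higher, 1 lower, percentile 100), among them Bnip3 (1.57), Egln3 (1.51), Ero1l (1.44) and the vascular growth factor Vegfa (1.32).

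The immunosuppressive and tissue-repair list split, with 10 of 18 members higher and 8 lower (median 0.43, percentile 100). Arg1 (3.34), Spp1 (3.09) and the elastase Mmp12 (2.33) were higher, and Lyve1, a hyaluronan receptor of resident macrophages, was lower (-4.92, and -2.08 in monocyte-like subclusters alone). TAM receptors, ligands and efferocytosis genes had a median of -0.39 (4 of 12 higher, 8 lower, percentile 8.68). The bridging ligands Gas6 (-2.25), Pros1 (-1.85) and Mfge8 (-1.55) were lower, and the scavenger receptor Cd36 (1.52) higher. Lipid handling and lysosome genes had a median of 0.47 (11 of 14 higher, 2 lower, percentile 99.8). The cathepsin Ctsl (1.84), the cholesterol exporter Abca1 (1.54), Fabp5 (1.51) and Lgals3 (1.05) were higher. Over the settings Fabp5 ranged from 0.486 to 1.83, Cd36 from 0.730 to 1.83 and Mmp12 from 1.61 to 2.71. Complement and resident macrophage genes went both ways (5 of 12 higher, 5 lower, median -0.05, percentile 62.3), with C3 (1.20) and C5ar1 (0.98) higher, and Selenop (-1.07), C1qc (-0.88) and C1qa (-0.77) lower. In monocyte-like subclusters alone Axl (0.95), Mertk (0.72), C1qa (0.67) and C1qc (0.83) were higher in 6C5, and C3 (-0.22) and the MHC class II median (-0.66) lower. The monocyte-like cells themselves lay in different subclusters, 84.1% of PBS cells in one marked by Ace and Treml4 and 76.3% of 6C5 cells in one marked by Arg1, Spp1, Rsad2 and the platelet gene Ppbp, so these values compare different kinds of cells.

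Cell cycle genes had a median of -1.90, with 18 of 18 members lower and the median at percentile 0, among them Ccnb2 (-2.34), Birc5 (-2.22), Stmn1 (-2.16) and Pclaf (-2.15). In monocyte-like subclusters alone the median was -0.26, with 7 members measured, 1 higher and 1 lower. A subcluster led by cell cycle genes held 275 of the 1826 PBS cells (15.1%) and 57 of the 1894 6C5 cells (3.01%). The highest genes beyond the lists were AA467197 (3.18), Gm15056 (3.05) and Pdpn (2.77), and the lowest were Ptprm (-4.10), Negr1 (-3.92), Klra17 (-3.64) and Epor (-3.58). In monocyte-like subclusters alone Ptprm (-1.37), Negr1 (-1.26) and Klra17 (-1.003) were less low, and Gm15056 was at 1.57 in macrophage-like subclusters alone. Cd274, which encodes PD-L1, was 1.78-fold higher (1.71 to 1.86). The other lists had medians of 0.37 for MHC class II presentation, 0.33 for checkpoint ligands, 0.23 for the interferon-gamma response (8 of 15 higher, 5 lower), 0.20 for MHC class I presentation, 0.18 for dissociation stress, -0.21 for the unfolded protein response and -0.09 for oxidative phosphorylation. With TMM factors the last 2 turned to 0.0906 and 0.23. In monocyte-like subclusters alone the unfolded protein response turned to 0.66, MHC class II to -0.66 and dissociation stress to -0.25. Different clusters held most of the class in each library. In PBS 39.8% of it lay in a cluster marked by Cd300e and Vcam1, and in 6C5 40.5% lay in a cluster marked by Ccl8 and Cxcl9 and 30.7% in a cluster marked by Arg1 and Spp1, so these ratios also carry the makeup of the class.

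**Figure D2:**
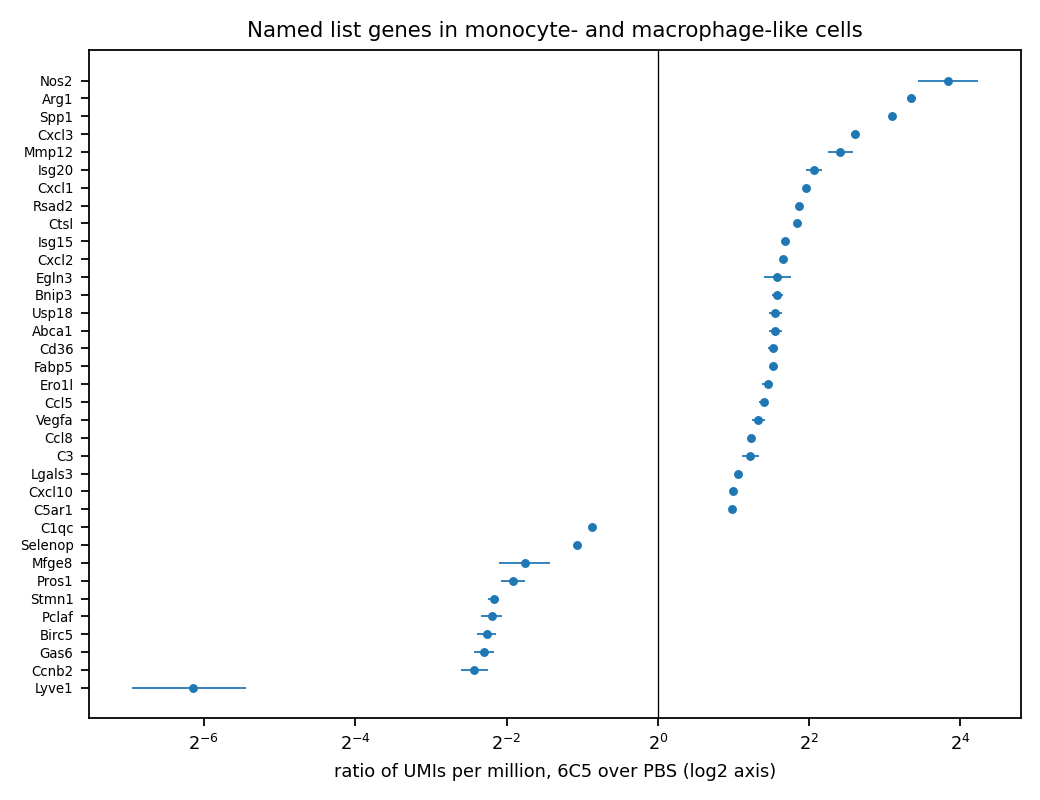
Ratio of CPM, 6C5 over PBS (horizontal log2 axis), of list genes in monocyte-like and macrophage-like cells. Points are ratios of summed counts from 1 library each, and bars are exact 95% intervals for counting error. Nos2 stands at 14.2 and Gas6 at 0.203, on either side of the line at 1.

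In DC-like cells (767 in PBS, 460 in 6C5), type I interferon-stimulated genes were higher in the 6C5 library in 20 of 20 measured members (median log2 ratio 0.86, percentile 100). Rsad2 (1.89), Ifit1, Ifit3 (1.38) and Ifit3b (1.34) led them. Inflammatory genes were higher in 15 of 15 members (median 0.66, percentile 100), with Cxcl3 (3.98), Cxcl2 (2.20), Cxcl1 (1.49) and Il12b (1.65), a subunit of interleukin 12. The maturation list had a median of 0.52 (11 of 16 higher, 2 lower, percentile 100), with the migration receptor Ccr7 (0.98), Fscn1 (0.80) and the costimulatory receptor Cd40 (0.76) higher. Its median was 0.50 in cDC1-like cells (12 of 15 higher, 2 lower), 0.31 in cDC2-like cells (8 of 15 higher, 0 lower) and -0.07 in mature DC-like cells (2 of 15 higher, 5 lower). The mature DC-like cluster, marked by Ccr7 and Fscn1, held 18.4% of the class in PBS and 37.2% in 6C5, so these ratios also carry its makeup. MHC class II genes had a median of -0.20 (2 of 8 higher, 6 lower, percentile 2.11), with H2-DMa (-0.56), H2-DMb1 (-0.51) and their activator Ciita (-0.56) lower, and Ctss (0.40) higher.

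Axl was higher in DC-like cells of the 6C5 library (ratio 1.49, 1.28 to 1.73), as were Cd274 (1.65, 1.55 to 1.76), Pdcd1 (1.85, 1.47 to 2.31), Arg1 (16.5, 13.3 to 20.8) and Spp1 (5.76, 5.35 to 6.21). In free RNA Arg1 was at 27.6 CPM in PBS and 314 in 6C5, and Spp1 at 285 and 1495.5. Free RNA was an estimated 1.62% and 1.27% of the UMIs of DC-like cells. RNA of monocyte-like or macrophage-like cells in DC-like cells was not tested. Slpi (log2 ratio 4.89), Clec4d (2.73) and Slfn4 (2.35) were among the highest genes, and the C-type lectins Cd209d (-2.97) and Cd209c (-1.83), with Gdf15 (-1.75), Lyz1 (-1.27), Adora3 (-1.25) and Nrg2 (-1.24), the lowest. With free-RNA-like barcodes left out Slpi fell to 2.45, Clec4d to 1.69 and Arg1 to 2.44 on the log2 scale. Gas6 (-1.47), C1qa (-0.51) and Gdf15 turned direction with at least 1000 UMIs. The other lists had medians of 0.94 for chemokines, 0.57 for the interferon-gamma response, 0.55 for immunosuppressive genes, 0.55 for complement, 0.47 for lipid handling, 0.45 for checkpoint ligands, 0.41 for hypoxia, 0.38 for MHC class I, 0.13 for oxidative phosphorylation, 0.02 for the unfolded protein response, -0.03 for dissociation stress and -0.16 for the cell cycle, and near 0 for TAM genes (5 of 11 higher, 4 lower). The complement median was 1.497 with at least 1000 UMIs, and the TAM, stress and unfolded protein response medians turned sign in some settings. The cDC2-like cluster held 41.7% of the class in PBS and 33.0% in 6C5.

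Neutrophil-like cells (528 in PBS, 1059 in 6C5) had the largest interferon list medians of the 6 classes. Type I interferon-stimulated genes had a median of 2.07, with 19 of 19 measured members higher in the 6C5 library (percentile 100). Ifit2 was at 18.0 CPM in PBS and 652 in 6C5 (ratio 36.2, 24.7 to 55.6), with Ifit3 (log2 ratio 4.07), Ifit3b (3.96) and Ifit1 (3.61) next. The interferon-gamma list had a median of 2.11 (11 of 12 higher, 1 lower, percentile 100), with Cxcl10 (4.06), Irgm1 (2.86), Gbp5 (2.79) and Gbp2 (2.64). Inflammatory genes had a median of 1.11 (11 of 13 higher, 2 lower, percentile 100), with Cxcl1 (3.53), Ccl4 (1.99), Tnf (1.90) and Nos2 (1.73). Hypoxia and glycolysis genes had a median of 1.16 (14 of 16 higher, 1 lower, percentile 100), with Ero1l (2.39), Bnip3 (2.37), P4ha1 (2.32) and Mif (2.22).

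Cd274 was 2.83-fold higher (2.57 to 3.11) in neutrophil-like cells of the 6C5 library, and Cmpk2 (3.64) was among the highest genes. Pi16 (-2.53), Dmxl2 (-2.17), R3hdm4 (-2.05), Hmgn2 (-1.98) and Sephs2 (-1.96) were among the lowest. C1qa (-2.26) and Selenop (-2.05) were lower too, but free RNA could supply 74.1% of the C1qa UMIs in PBS and 85.9% in 6C5. Other list medians were 0.68 for MHC class I, 0.52 for the unfolded protein response, 0.22 for lipid handling, 0.15 for checkpoint ligands, 0.02 for chemokines, -0.13 for dissociation stress, -0.18 for TAM genes, -0.32 for the cell cycle, -0.54 for oxidative phosphorylation, -0.68 for immunosuppressive genes, -0.82 for complement and -1.26 for MHC class II. With free RNA subtracted the MHC class II median turned to 0.15 and the immunosuppressive median to 0.06, and the chemokine median moved to 1.24. The complement median turned to 0.0101 with the wider free RNA profile and the unfolded protein response to -0.0657 at resolution 2. TMM factors turned the TAM (0.21), stress (0.28) and cell cycle (0.0906) medians. No direction is read from any of these 8 lists. The median of all genes was -0.25, and TMM factors moved it to 0.15. In PBS 65.9% of these cells lay in a cluster marked by Retnlg and S100a8. In 6C5 86.3% (34.1% in PBS) lay in a cluster marked by Il23a and Cstdc4. The interferon gene Ifit3b was also among the 10 leading genes of that cluster. The ratios in this class, its interferon medians included, therefore also carry the makeup of the class.

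In T-like cells (313 in PBS, 397 in 6C5), type I interferon-stimulated genes were higher in the 6C5 library, while cytotoxic and inhibitory receptor genes went both ways. Gzmb, a protease of cytotoxic granules, was 1.73-fold higher (1.61 to 1.86), and Ifng was lower (ratio 0.591, 0.521 to 0.670). Lag3 was 2.21-fold higher (1.95 to 2.51). Pdcd1, which encodes PD-1, was at 464 CPM in PBS and 425 in 6C5 (ratio 0.917, 0.852 to 0.988), a direction that turned when each cell was weighted equally (log2 ratio 0.06). The cytotoxic list had a median of -0.24 (6 of 16 higher, 8 lower, percentile 0.04), with Xcl1 (0.87) higher, and Gzmf (-1.60), Ccl4 (-0.89) and Ccl3 (-0.87) lower. When mixed subclusters were kept, the median of this list turned to 0.0893 and the log2 ratio of Ccl4 to 0.66.

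Inhibitory receptor genes had a median of -0.05 (5 of 14 higher, 6 lower, percentile 24.2), with Lag3 (1.14), Ctla4 (0.69), Havcr2 (0.59) and Tigit (0.52) among those higher. Genes of naive and memory cells also had a median of -0.05 (2 of 13 higher, 5 lower, percentile 26.9), with Ccr7 at 1.06, Id3 at -1.09, S1pr1 at -0.37 and Bcl2 at -0.35. The regulatory T cell list had a median of 0.23 (6 of 13 higher, 2 lower, percentile 99.7), with Tnfrsf4 (0.65), Ccr8 (0.55) and Tnfrsf18 (0.46) higher and Itgae (-2.22) lower. Regulatory T-like cells were 35 of 313 T-like cells in PBS and 61 of 397 in 6C5, so the values of this list also carry that share. Foxp3 was at 55.4 and 62.5 CPM (ratio 1.13, 0.918 to 1.39). Type I interferon-stimulated genes had a median of 0.95 (15 of 19 higher, 0 lower, percentile 100), with Isg15 (1.57), Oas3 (1.47), Ifit1 (1.46) and Ifi27l2a (1.35). Ltf (2.24), Serpine2 (2.22) and Sv2c (1.67) were the highest ranked genes and Il17a the lowest (-3.73). Il17a led a gamma-delta T-like or ILC-like subcluster of only 14 PBS and 13 6C5 cells, a small part of the class. Lyz2 (-1.30), C1qa (-1.97) and the MHC class II genes H2-Ab1 (-2.01), H2-Eb1 (-1.63), H2-Aa (-1.48) and Cd74 (-1.22) were also lower. Free RNA could supply 74.7% of the C1qa UMIs in PBS and 96.9% in 6C5, and all of these but C1qa turned direction when mixed subclusters were kept.

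After thinning to 1000 UMIs, 17.9% (13.7 to 22.6) of PBS and 26.5% (22.2 to 31.1) of 6C5 T-like cells had a Gzmb UMI, and 119 of 313 and 203 of 397 cells without thinning. For Lag3 the thinned shares were 9.09% and 15.3%, and the unthinned shares 30.0% and 42.8%. For Pdcd1 the thinned shares were 22.1% and 19.8% and the unthinned shares 48.2% and 54.2%, and no order is read from them. Median depths of the thinned cells were 5791 and 5861 UMIs, and 5 PBS and 4 6C5 cells were left out. In B-like cells, which should lack Gzmb, 0 of 244 PBS and 0 of 229 6C5 cells had such a UMI, which allows shares of up to 1.23% and 1.31%. Their median depths were 2741.5 and 2471 UMIs. For Lag3, 0.410% of PBS B-like cells had a UMI.

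In CD8 T-like cells (204 and 283), Gzmb was 1.77-fold higher (1.63 to 1.92) and Ifng lower (ratio 0.579, 0.507 to 0.661) in the 6C5 library. Type I interferon-stimulated genes had a median of 0.70 (13 of 17 higher, 0 lower, percentile 100), with Ifi27l2a (1.57), Oas3 (0.96), Xaf1 (0.90) and Isg15 (0.88). The cytotoxic list had a median of 0.03 (7 of 16 higher, 5 lower, percentile 70.3). Xcl1 (0.96, and 0.2242 to 1.625 over the settings) was higher and Gzmf (-1.63), Ccl4 (-0.90) and Ccl3 (-0.86) lower. Inhibitory receptor genes had a median of 0.01 (4 of 14 higher, 5 lower, percentile 58.0), with Lag3 (1.18), Havcr2 (0.51), Tox (0.45) and Tigit (0.44) higher. A subcluster marked by Lag3, Havcr2 and Ltf held 46 of 204 PBS and 97 of 283 6C5 cells (22.5% and 34.3%), and the cycling subcluster 17.6% and 12.0%, so these ratios carry that makeup. Pdcd1 (-0.14) turned to 0.08 when each cell was weighted equally. Cell cycle genes had a median of -0.20 (0 of 18 higher, 8 lower, percentile 0.34), with Ccnb1 (-0.79), Cdk1 (-0.65) and Ccnb2 (-0.61). Ltf (2.47), Serpine2 (2.26) and Ap3b1 (1.22) were among the highest genes. Serpina3g (-1.70) and Cxcl10 (-1.39, and -2.14 to -0.4325 over the settings) were among the lowest. The MHC class II genes H2-Ab1 (-2.44), H2-Eb1 (-1.96), H2-Aa (-1.89) and Cd74 (-1.76) were lower still, and their source was not tested.

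Other list medians in T-like cells were 0.15 for the interferon-gamma response, 0.15 for oxidative phosphorylation, 0.03 for hypoxia, 0.02 for the cell cycle, -0.01 for MHC class I, -0.10 for dissociation stress, -0.12 for the unfolded protein response and -0.13 for activation. In CD8 T-like cells they were 0.33 for the regulatory programme, 0.18 for dissociation stress, 0.17 for the interferon-gamma response, 0.13 for activation, 0.11 for oxidative phosphorylation, 0.10 for naive and memory genes, -0.07 for MHC class I, -0.17 for the unfolded protein response and -0.22 for hypoxia. In T-like cells the hypoxia, cell cycle, MHC class I, stress, unfolded protein response, cytotoxic, inhibitory receptor and regulatory values turned sign in at least 1 setting, as did the cytotoxic, inhibitory receptor and stress values in CD8 T-like cells. A cluster marked by Tcf7 and Lef1 held 60.1% of PBS and 50.1% of 6C5 T-like cells.

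In NK-like cells (259 and 248), type I interferon-stimulated genes were higher in the 6C5 library and granzyme genes split. The interferon list had a median of 0.74 (13 of 18 higher, 0 lower, percentile 100), with Ifit1 (2.46), Rsad2 (1.92), Ifi44 (1.44) and Usp18 (1.25). Gzmb was 1.67-fold higher (1.55 to 1.79) and Gzmc 1.82-fold higher (1.73 to 1.92), whereas Gzmd was 13.1-fold lower (9.67 to 18.0) and Gzme 6.51-fold lower (4.76 to 9.09). The cytotoxic list had a median of -0.06 (2 of 15 higher, 7 lower, percentile 18.4), with Gzmk (-1.08) and Ccl3 (-0.99) lower. Ifng had a ratio of 0.979 (0.818 to 1.17). The dissociation and heat-shock list had a median of -0.24 (3 of 15 higher, 7 lower, percentile 0.11), with Hspa1b (-1.19), Dnajb1 (-0.57), Dusp1 (-0.53) and Fos (-0.50) lower. Cxcl2 (2.95), Cxcl10 (2.12), Hilpda (1.23) and Serpinb9b (1.10) were among the highest genes, but Cxcl2 ranged from 1.07 with free-RNA-like barcodes left out to 5.71 with the wider free RNA profile subtracted. Lyz2 (-2.11), H2-Ab1 (-1.30) and Cd74 (-1.20), genes of myeloid cells, were among the lowest, with H2-Ab1 at -0.12 when doublets were kept. Over the settings Lyz2 ranged from -5.387 to -1.255 and Cd74 from -2.009 to -0.198. Shares of NK-like cells with a Lag3 UMI were 1.94% and 1.63% thinned and 8.88% and 14.5% unthinned, so no order is read from them. The remaining medians were 0.20 for oxidative phosphorylation, 0.12 for hypoxia, 0.08 for the interferon-gamma response, 0.05 for the cell cycle, -0.03 for the unfolded protein response and -0.05 for MHC class I. The cytotoxic, unfolded protein response and MHC class I medians turned sign with TMM factors. A subcluster of 9 PBS and 17 6C5 cells was led by interferon genes, among them Cxcl10, Usp18 and Ifi44. Another, led by Gzmc and Serpinb9b, held 43 and 57 cells. The ratios in this class therefore also carry its makeup, and how much each subcluster adds was not tested.

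**Figure D3:**
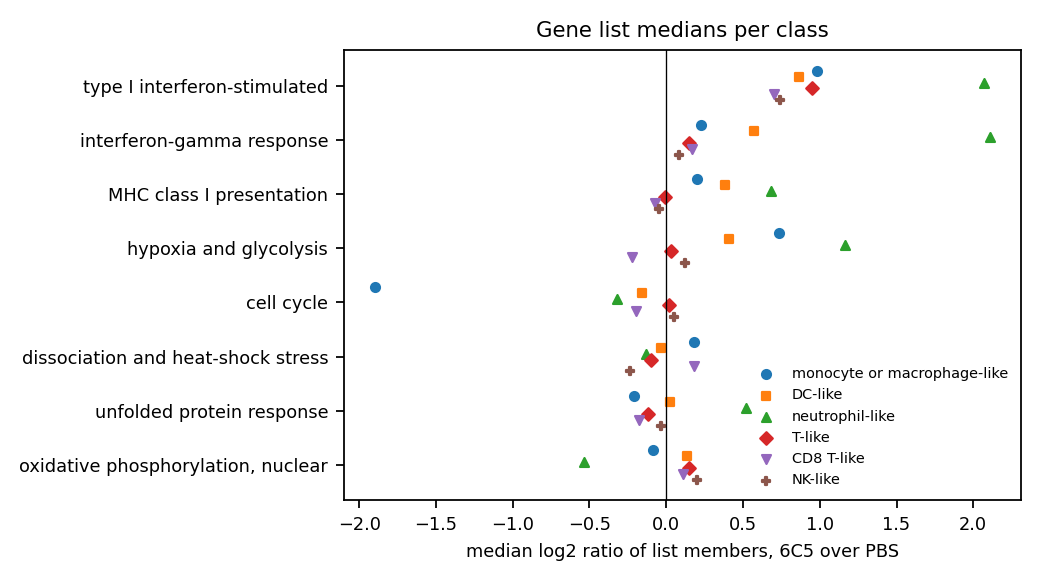
Median log2 ratio of list members, 6C5 over PBS (horizontal axis), for the lists measured in all 6 classes. Each symbol is a class, from 1 library per group. The type I interferon-stimulated medians lie right of 0 in every class, from 0.70 in CD8 T-like cells to 2.07 in neutrophil-like cells, and the cell cycle median of monocyte-like and macrophage-like cells lies at -1.90.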

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

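All tests in this part were chosen after the results had been seen. Melanoma-like cells appeared in a sort for CD45, which tumour cells should lack. They were 176 of 4403 named, mixed and melanoma-like barcodes in PBS (4.00%, 3.44 to 4.62) and 382 of 5000 in 6C5 (7.64%, 6.92 to 8.41), a signal outside the immune classes that was higher in the 6C5 library.

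Type I interferon-stimulated genes were higher in the 6C5 library in all 6 classes. Free RNA is argued against, since after its subtraction the lowest of the 6 medians was 0.715. RNA of macrophage-like cells is argued against too, for the T and NK cells kept. There macrophage markers allowed at most 0.0975 of the RNA share that the interferon genes would need. T and NK barcodes led by macrophage markers had already been left out as mixed. RNA of monocyte-like cells or neutrophils was not tested. An effect of the antibody cannot be told apart from any other difference between the mice or libraries, since there was 1 library per group. An interferon response to treatment therefore stays a hypothesis.

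Cell cycle genes were lower in monocyte-like and macrophage-like cells of the 6C5 library. The removal of doublets is argued against, since the median was -1.91 with doublets kept. A difference of the whole library is argued against, since the lowest median among T, CD8 T, NK and DC classes was -0.20. A loss of the cycling subcluster alone could account for only part, since without it the median was -1.48 and 18 of 18 members stayed lower. That test leaves other differences in makeup in place. A macrophage-like subcluster marked by Cd300e and Vcam1 held 550 PBS and 7 6C5 cells. How much of the difference comes from the makeup of the class was therefore not settled. In monocyte-like subclusters alone the median was -0.26, and an effect of treatment on proliferation was not tested, with 1 library per group.

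The neutrophil share was higher in the 6C5 library. A UMI minimum that removed small PBS cells is argued against, since the ratio was 1.88 with at least 300 UMIs and 200 genes. The size of the ratio moved between settings, which change the barcodes kept as well as the clusters named neutrophil, and these were not separated. Its lowest value over the settings run was 1.26. The sort and tissue digestion, each done for 1 library per group, cannot be told apart from the treatment.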

How the results depend on the processing

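No paired analysis was possible because each group has 1 library and no test was run. Gene ratios gave 2410 values for 213 results (1901 the same, 482 moved, 27 reversed), list medians 1278 for 84 (1242, 36 and 0, where only a median whose interval excludes 0 can count as reversed), shares 207 for 18 (174, 21 and 12), and shares of cells with a UMI 48 for 24 (15, 33 and 0). The following alternatives were chosen after seeing the data: mixed subclusters kept, free-RNA-like barcodes left out, a wider free RNA profile, and macrophage-like or monocyte-like subclusters alone. With mixed subclusters kept, the counts of cells per subclass did not change, so that setting does not test the subclass counts. Cd8a, Gzmb, Cxcl13 and Epor have no value in monocyte-like subclusters alone, where both sums were 3 UMIs or fewer. Same means inside the interval of the main value, which for a list comes from the spread of its members and can be wide. In neutrophil-like cells the TAM and cell cycle lists had unbounded intervals, so any value counted as the same. Without regard to intervals, 74 values of 30 lists had the other sign. The cause was not tested for the values below, which are ratios of shares or log2 ratios, 6C5 over PBS.

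With order-of-magnitude cell calling the ratio was 1.53 for T-like, 2.09 for NK-like, 0.740 for DC-like and 3.56 for neutrophil-like cells, 0.774 for CD8 T and 1.18 for NK cells among T and NK cells, and 0.750 for monocytes, 1.20 for macrophages, 0.713 for cDC1 and 0.746 for cDC2. With 1000 variable genes it was 1.48 for T-like and 0.909 for monocyte-like and macrophage-like cells, 1.01 for CD8 T and 0.724 for NK cells among T and NK cells, 1.74 for monocytes and 0.473 for CD8 T per regulatory T cell. With resolution 2 it was 0.624 for DC-like, 1.06 for monocyte-like and macrophage-like and 1.26 for neutrophil-like cells, and the log2 ratio of C1qa in DC was 0.0143. With each library clustered on its own it was 0.654 for DC-like cells, 0.634 for monocytes, 1.39 for macrophages and 0.888 (0.764 to 1.03) for cDC2. With resolution 0.5 it was 0.743 for monocytes and 1.34 for macrophages, and with at least 300 UMIs and 200 genes 2.91 and 0.883. With doublets kept cDC2 was at 0.412.

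With at least 1000 UMIs the ratio was 0.753 for monocytes and 1.15 for macrophages, the type I interferon-stimulated median in CD8 T was 0.86 and the complement median in DC 1.497, Gas6 (0.15), C1qa (1.01) and Gdf15 (0.37) in DC turned, and Cxcl9 in neutrophil was at 0.24. With at most 5% mitochondrial UMIs monocytes were at 1.51 and the log2 ratio of Cxcl9 in neutrophil was 0.0507. With free-RNA-like barcodes left out monocytes were at 0.770 and macrophages at 1.28, the type I interferon-stimulated median in NK was 0.49 and the inflammatory median in DC 0.38, C1qa in DC was at 0.81 and Cxcl9 in neutrophil at 0.38. With monocyte-like subclusters alone Axl (0.95), Mertk (0.72), C1qa (0.67), C1qc (0.83) and C3 (-0.22) turned, and medians were 1.58 for type I interferon-stimulated, 0.83 for complement, 1.28 for chemokines, -0.26 for cell cycle, 0.93 for interferon-gamma, -0.66 for MHC class II, 0.44 for MHC class I, -0.25 for stress and 0.66 for unfolded protein response genes. With macrophage-like subclusters alone the hypoxia median was 0.56. With TMM factors Mertk in monocyte or macrophage was at 0.0847, and medians were 1.30 for type I interferon-stimulated, 0.54 for interferon-gamma, 0.69 for MHC class II, 0.52 for MHC class I, 1.14 for chemokine, 0.50 for stress and 0.23 for oxidative phosphorylation genes there. They were 0.0213 for MHC class I in NK, and 1.09 for MHC class I and -0.13 for oxidative phosphorylation in neutrophil. The cell cycle median was -2.17 with each cell weighted equally and -1.37 with a pseudocount of 10 CPM. With each cell weighted equally Pdcd1 was at 0.0621 in T and 0.0766 in CD8 T, and the MHC class I median in NK was 0.0561. In neutrophil the MHC class I median was 1.16 with resolution 2. With free RNA subtracted it was 1.13 and the chemokine median 1.24, and with the wider profile 1.11 and 1.46, with MHC class II at 1.12. With free RNA subtracted Spp1 in T was at -0.41, and with the wider profile at -0.39, where Cd8a in monocyte or macrophage was at 0.00. With mixed subclusters kept Ccl4 (0.66), Id3 (0.12), H2-Ab1 (0.0697), H2-Eb1 (0.34), H2-Aa (0.26), Lyz2 (0.20) and Cd74 (0.14) in T and Cxcl9 in DC (0.0347) turned, and medians in T were 0.40 for hypoxia, -0.24 for cell cycle and 0.22 for stress genes.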

Other observations

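Melanoma-like cells that came through the sort carried more cell cycle RNA in the 6C5 library. Cell cycle genes had a median log2 ratio of 0.82 with 18 of 18 members higher, among them Top2a (1.55) and Mki67 (1.14). The melanoma markers Mlana (-0.80), Pmel (-0.59), Dct (-0.43) and Tyrp1 (-0.43) were lower, as was mouse Axl (-0.84). The MHC class I genes H2-K1 (0.56), H2-D1 (0.45) and B2m (0.33) were higher, but the MHC class I list had a median of only 0.14 (7 of 15 higher, 0 lower). Human AXL, which the line is named for, is not in the mouse gene table and was not analysed here.

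In cDC1-like cells of the 6C5 library Il12b was 21.5-fold higher (14.3 to 33.5), with Ccr7 (1.40) and Cd40 (1.05) also higher. In mature DC-like cells Ccl22 (-1.17) and Cxcl9 (-1.38) were lower, and in cDC2-like cells Cd209d (-2.91) was lower and Cd36 (2.64) higher. Type I interferon-stimulated medians were 0.64 in cDC1-like, 0.98 in cDC2-like and 0.77 in mature DC-like cells, and no difference between the subclasses was tested. In monocyte-like cells alone this median was 1.58 with 20 of 20 members higher, led by Ifi44 (3.43), and Isg15 was at 2.25. Most PBS monocyte-like cells (195 of 232) lay in a subcluster marked by Ace and most 6C5 cells (400 of 524) in one marked by Arg1, the platelet gene Ppbp and interferon genes such as Rsad2 and Ifit2, so this median compares different subclusters. B-like cells had a smaller median of 0.30 (4 of 14 higher), and a stress median of -0.35 (10 of 15 lower), with Atf3 (-1.66), Fosb (-0.70) and Jun (-0.36). Lyz2 (-2.02), C1qc (-1.71) and C1qa (-1.13) were lower in B-like cells, which should not make them, so free RNA itself differed between the libraries.

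Barcodes with both T-cell and macrophage genes in the T and NK subclusters numbered 49 in PBS and 119 in 6C5. An unnamed cluster of 599 PBS and 530 6C5 barcodes was led by genes such as Plcb1 and Cacna1d. Both libraries carried Xist (11124 UMIs in PBS, 6362 in 6C5), and Y-linked genes had 0 UMIs in PBS and 1 in 6C5, the pattern of female mice.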
